A study of Homo sapiens with 41 samples.

How the data were processed

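Blood RNA from people in 4 groups was sequenced after library preparation with a stranded total RNA kit, which keeps unspliced and non-coding RNA as well as messenger RNA. The labels name the groups normal (12 libraries), cellular (13), humoral (12) and mixed (4). The source name of the normal group is normal and its group tag normal rejection, so the labels leave open who these individuals were. They give no transplanted organ and do not state that each library came from a separate person. The p-values therefore measure the spread between these samples, part of which may be technical.

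The values used were whole-number counts of reads per gene, deposited by the authors as 3 tables of all 41 libraries, with counts on the forward strand, on the reverse strand and over both strands. The submitters' processing notes name FastQC, STAR, edgeR, R 3.2.1 and the genome build GRCh38.p3. The program that counted reads, the gene annotation release and the treatment of reads that map to several places were not given in the sources used here. Values of genes with near-identical copies (globins, ribosomal protein genes, GAPDH, small nucleolar RNA genes and processed pseudogenes) are therefore uncertain. Kits of this type give reads from the strand opposite to the transcript, and the reverse-strand table held 663046741 counts against 41570188 in the forward-strand table, so the reverse-strand counts were taken as sense counts. The table over both strands (649720794 counts) served as an alternative.

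Of 66023 gene identifiers, 56927 were found in GENCODE release 29, which supplied symbols and GRCh38 coordinates, and 9096 were not. 515 identifiers of Y-linked genes, XIST and its antisense gene were left out because the samples come from people. Total sense counts ranged from 5838124 to 38638043 per library. Intervals and lower bounds that rest on counts cover counting error only, because reads without molecular identifiers are not independent molecules.

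Sense counts were normalised with the trimmed mean of M-values (TMM) and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with all 41 libraries in 1 fit and no covariate. Genes were kept with filterByExpr (minimum count 10 in a number of libraries set by the smallest group of 4, minimum total 15), which left 19576 genes, 13450 of them coding. Each of the 6 pairs of groups was tested with the quasi-likelihood F test, and a joint test covered any difference among the 4 groups. Adjusted p-values follow Benjamini and Hochberg within a comparison, with a threshold of 0.05. Levels are TMM-normalised CPM (read counts scaled to a common library total), as mean ± SD over libraries, and fold changes are on the log2 scale with their standard error (SE). Where every library of a group had a count of 0, the fold is a lower bound computed against a floor of 3 counts over the group.

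26 gene lists covering blood cell types, interferon responses, antigen presentation, other responses, published rejection gene sets, mitochondrially encoded genes and ribosomal proteins were tested with camera of limma 3.58.1, which asks whether a list is displaced relative to all other genes. Camera ran with its preset correlation between genes of 0.01 and was repeated with a correlation estimated from the data, and fry tested whether the genes of a list moved on balance in 1 direction. P-values were adjusted over the 26 lists within a comparison. For each list the number of members past the gene test is given over all genes and adjusted over the list alone. A list score per library is the mean log2 CPM of the members (prior count 2) relative to the mean of the normal libraries.

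The groups, tests, lists, named-gene rule and part of the alternatives were fixed before the data were examined. Named genes were chosen per comparison among genes with a symbol, an adjusted p past the threshold and group medians of CPM that differed in the direction of the fold change. The 10 with the smallest p that were higher and the 10 that were lower were taken, or all where fewer passed. Where fewer than 5 passed, the 3 genes with the smallest p in each direction were taken as values that did not pass. For each list past the threshold of camera, the 3 members with the smallest p were added. A few of the genes chosen in this way are not reported here.

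A technical grouping of the libraries was defined after the data were examined. The share of counts in 880 genes annotated as sense-intronic, which reflects unspliced RNA, was computed per library, and the libraries were split at the widest gap of its log2 value into an intron-rich and an intron-poor class. Library measures were compared between groups with two-sided permutation tests of the difference of means (exact with the mixed group, otherwise 100000 resamples), adjusted over 21 tests. List scores of called lists were compared in the same way, adjusted over 43 tests, and these tests were also chosen after the camera results were seen.

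Alternatives fixed beforehand were the size factors of DESeq2, TMM without globin genes or without immunoglobulin and T cell receptor segments, DESeq2 1.42.0 and limma-voom with quality weights as other tools, no low-count filter, a stricter filter (CPM of at least 1 in 12 libraries), counts over both strands, the globin share as a covariate, surrogate variables (sva 3.50.0, 6 variables), the replicate number as a block, fits of only the 2 groups compared, a fold-change minimum, and leaving out each library in turn. Alternatives chosen after the data were examined were the library class as a term, the log2 intronic share as a covariate, the 29 intron-poor or the 12 intron-rich libraries alone, thinning of all libraries to the smallest total, and leaving out 2 libraries with reads in 19 long coding genes that blood cells hardly transcribe. In other splits of the samples, the 41 group labels were shuffled and the whole fit repeated, for 60 splits including the real one.

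Duplicate deposits were checked with a chi-square test between all 216 pairs of libraries within a group over genes with at least 10 counts. The smallest chi-square per degree of freedom was 22.2, so no pair agreed within sampling noise. The procedure was tested on simulated counts for the same 19576 genes and groups, with 100 genes changed 2-fold and 100 changed 4-fold. Of these, 41% and 73% were called for cellular against normal, 48% and 70% for humoral against normal, and 24% and 65% for mixed against normal. Of the unchanged genes, 6 of 19357, 7 of 19356 and 1 of 19356 were called.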

Results

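Gene expression in blood was measured by stranded total RNA sequencing in 41 libraries, 12 labelled normal, 13 cellular, 12 humoral and 4 mixed. The series concerns the mechanism of cellular and humoral rejection of a transplant. Cellular rejection is driven mainly by T cells that attack the graft, humoral rejection by antibodies against the donor, and mixed rejection has features of both. Total sense counts ranged from 5838124 to 38638043 per library, with medians of 20183658 for normal, 12025543 for cellular, 9819581.5 for humoral and 16724459.5 for mixed libraries. The lower depth of the humoral libraries passed a permutation test against normal (p = 0.00344, adjusted p = 0.0144 over 21 tests).

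The libraries also differed in unspliced RNA. The share of counts in sense-intronic genes had a gap between 0.107% and 0.167%, which separated 12 intron-rich from 29 intron-poor libraries. The intron-rich class held 8 of 12 humoral, 3 of 13 cellular, 1 of 12 normal and 0 of 4 mixed libraries (Fisher's exact test over the 4 groups, p = 0.00897). For humoral against normal the exact p was 0.00942 (adjusted p = 0.0565 over the 6 pairs of groups). Median sense-intronic shares were 0.223% in humoral and 0.0715% in normal libraries. Median shares of counts in mitochondrially encoded genes were 0.601% and 1.52%, and those in ribosomal protein genes 0.822% and 1.51% (permutation tests, adjusted p = 0.00756 for each of the 3 measures).

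**Figure D1:**
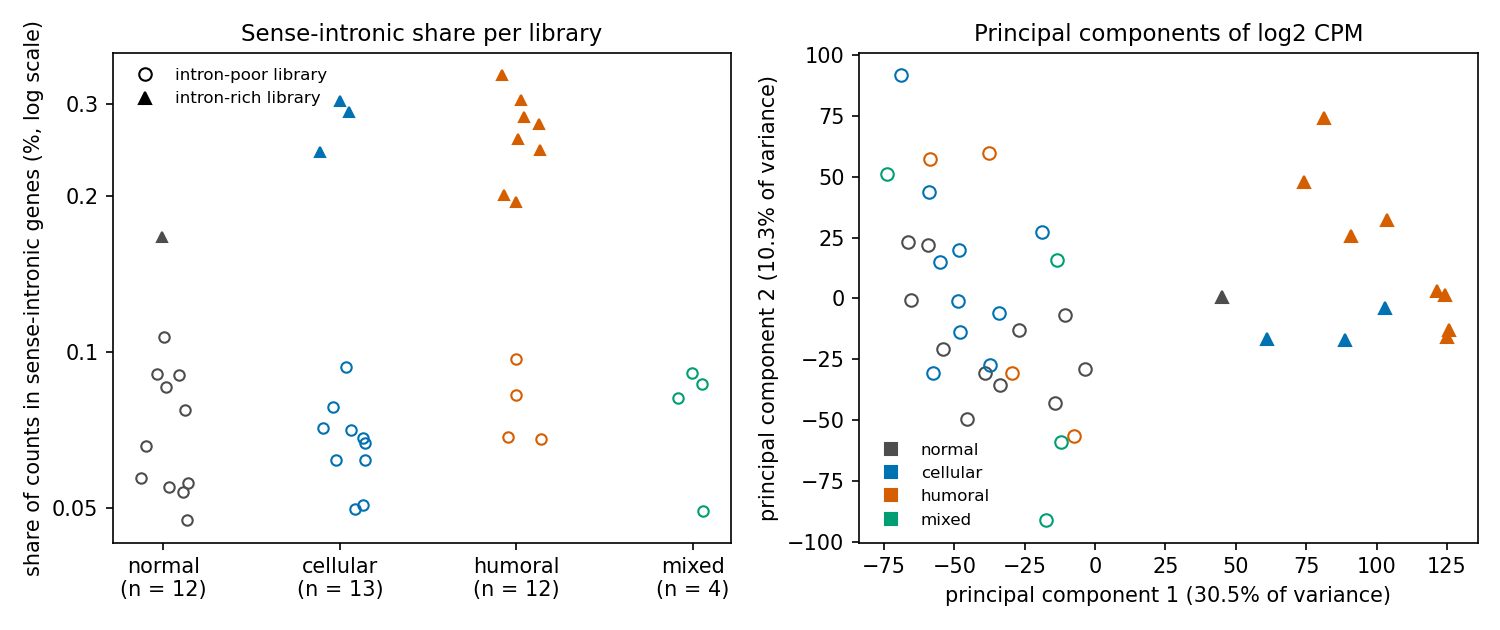
Left, share of counts in sense-intronic genes (%, log scale) for each library by group, and right, principal components 1 (30.5% of variance) and 2 (10.3%) of log2 CPM. Each point is 1 library, coloured by group, with open circles for the 29 intron-poor and filled triangles for the 12 intron-rich libraries, of which 8 were humoral.

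The comparison of cellular with normal libraries asks how blood differs during rejection driven by T cells. Camera with its preset correlation called T cell and cytotoxic lymphocyte lists lower, and a list of genes that glucocorticoids induce higher, in cellular libraries. None of the 5 lists it called passed with an estimated correlation (adjusted p from 0.512), fry (from 0.496) or per-library scores (from 0.0798). In the cytotoxic and NK cell list, PRF1, which encodes the pore-forming protein perforin, measured 143 ± 61.2 CPM in cellular and 236 ± 93.9 CPM in normal libraries (SD, n = 13 and 12). TBX21, a transcription factor of effector lymphocytes, measured 28.02 ± 12.7 against 48.0 ± 18.7 CPM, and S1PR5, a receptor that guides NK cells, 20.8 ± 8.05 against 36.2 ± 15.9 CPM. The list had a median log2 fold change of −0.57 (camera adjusted p = 1.13e-10, 0.512 with an estimated correlation). None of its 20 members passed over all genes, and 7 were lower when adjusted over the list alone. In the T cell list the signalling chain CD247 measured 92.9 ± 30.7 against 148 ± 50.3 CPM, and the surface receptors CD2 and CD5 had log2 fold changes of −0.54 and −0.56. The T cell median was −0.32 over 18 genes (camera adjusted p = 4.94e-06, 0.807 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone.

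The glucocorticoid response list had a median of 0.85 in cellular against normal libraries over 13 genes (camera adjusted p = 0.000797, 0.807 with an estimated correlation). 0 of its members passed over all genes and 2 adjusted over the list alone. Its leading members were OLAH (4.17 ± 4.37 against 0.798 ± 0.642 CPM), TPST1 (38.7 ± 47.4 against 13.1 ± 10.1 CPM) and the decoy receptor for interleukin 1, IL1R2 (231 ± 311 against 102 ± 52.3 CPM; SD, n = 13 and 12). Without cellular replicate 2 the list median was 0.57 and the call was lost (adjusted p = 0.0957). Plasma cell genes, led by XBP1 (86.2 ± 31.6 against 119 ± 30.7 CPM), PDIA4 (log2 −0.46) and SEC11C (log2 −0.32), which serve antibody secretion, had a median of −0.32 over 12 genes (camera adjusted p = 0.0259, 0.807 with an estimated correlation). 0 passed over all genes or adjusted over the list alone. The plasma cell call was lost without cellular replicate 10 (adjusted p = 0.0842), cellular replicate 2 (0.0719), normal replicate 3 (0.0730) or normal replicate 5 (0.0519). Ribosomal protein genes had a median of −0.20 over 31 genes (camera adjusted p = 4.94e-06, 0.878 with an estimated correlation). Log2 fold changes were −0.82 for RPS16, −0.52 for RPL22 and −0.39 for RPL14, with 0 members past the threshold over all genes or adjusted over the list alone. The ribosomal median was −0.31 without cellular replicate 11, −0.10 without cellular replicate 12, −0.13 without cellular replicate 4, −0.09 without cellular replicate 5 and −0.11 without normal replicate 3. Among intron-poor libraries it was 0.01 (adjusted p = 0.724).

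Single genes hardly separated cellular from normal libraries. edgeR called 3 genes (2 higher, 1 lower) of 19576, beside 940 at an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 0. ADGRG7 (ENSG00000144820.7, chromosome 3, 100609589 to 100695479), an adhesion G protein-coupled receptor, measured 9.98 ± 20.97 CPM in cellular against 0.0300 ± 0.0591 CPM in normal libraries, with a log2 fold change of 8.19 (SE 1.35, adjusted p = 0.00631). It exceeded 1 CPM in 3 of 13 cellular and 0 of 12 normal libraries. SNORD3C (ENSG00000264940.4, chromosome 17, 19189665 to 19190245), a small nucleolar RNA gene with near-identical copies, measured 22.1 ± 78.1 against 0.353 ± 0.224 CPM (log2 5.96, SE 1.13, adjusted p = 0.0288) and exceeded 1 CPM in 2 of 13 cellular libraries. Without cellular replicate 8 its log2 fold change was 0.34 (adjusted p = 0.858), and without any 1 of the 12 normal libraries its adjusted p lay between 0.0523 and 0.0806. The gene that was lower, ENSG00000233209.6, has no symbol in the annotation used and was chosen after its values were seen (log2 −5.48, adjusted p = 0.0158, 0.0221 ± 0.0680 against 1.10 ± 1.55 CPM). The count fell to 1 gene without normal replicate 3 or normal replicate 9. Genes next in order of p did not pass. Among them were PXDNL (log2 2.74, adjusted p = 0.566) and the T cell receptor delta constant gene TRDC (21.5 ± 8.08 against 44.1 ± 17.5 CPM, adjusted p = 0.588). ERBB2 measured 5.12 ± 1.68 against 9.64 ± 4.61 CPM and the tyrosyl-tRNA synthetase YARS1 26.1 ± 5.38 against 36.3 ± 5.48 CPM (adjusted p = 0.867 for both).

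Humoral libraries, from the antibody-driven form of rejection, differed from normal in 6260 of 19576 genes (32.0%), 3418 higher and 2842 lower (edgeR). Camera called cytotoxic lymphocyte, classical monocyte, immature neutrophil granule and ribosomal protein lists lower, none with an estimated correlation. GZMB (ENSG00000100453.12, chromosome 14, 24630954 to 24634267), which encodes the killing enzyme granzyme B, fell from 76.4 ± 37.5 to 25.99 ± 16.6 CPM (log2 −1.55, SE 0.30, adjusted p = 0.000799; SD, n = 12 and 12). PRF1 fell from 236 ± 93.9 to 105 ± 68.0 CPM (log2 −1.17, SE 0.26, adjusted p = 0.0017). S1PR5 fell from 36.2 ± 15.9 to 14.2 ± 10.97 CPM (log2 −1.35, adjusted p = 0.00143). HCST, the signalling adaptor of an activating receptor of NK cells, fell from 20.9 ± 5.71 to 9.37 ± 3.78 CPM (log2 −1.15, SE 0.18, adjusted p = 0.000462). Of 20 cytotoxic and NK cell genes, 11 were lower over all genes and 11 adjusted over the list alone, with a median of −0.79 (camera adjusted p = 6.08e-06, 0.777 with an estimated correlation, fry adjusted p = 0.00283).

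Classical monocyte genes had a median of −0.56 in humoral against normal libraries (camera adjusted p = 0.00171, 0.777 with an estimated correlation, fry adjusted p = 0.00283). 4 of 12 members fell over all genes and 5 adjusted over the list alone. LYZ, the gene of lysozyme, fell from 4786 ± 1525 to 1936 ± 1584 CPM (log2 −1.31, SE 0.29, adjusted p = 0.00154; SD, n = 12 and 12). CD14, a co-receptor for bacterial lipopolysaccharide, fell from 193 ± 56.5 to 80.7 ± 36.6 CPM (log2 −1.26, SE 0.28, adjusted p = 0.00162). The lectin gene FCN1 fell from 1106 ± 541 to 596 ± 236 CPM (log2 −0.89, adjusted p = 0.00595). Immature neutrophil granule genes had the lowest median, −1.67 (camera adjusted p = 0.000941, 0.972 with an estimated correlation, fry adjusted p = 0.124), with 11 of 18 members lower over all genes and 13 adjusted over the list alone. OLFM4, found in a subset of neutrophils, fell from 45.4 ± 79.8 to 7.35 ± 7.95 CPM (log2 −2.63, SE 0.73, adjusted p = 0.00636). CAMP, the gene of the antimicrobial peptide cathelicidin, fell from 97.3 ± 182 to 22.3 ± 19.5 CPM (log2 −2.13, adjusted p = 0.00853), and the resistin gene RETN had a log2 fold change of −1.76 (adjusted p = 0.0055). Without normal replicate 1 the granule list median was −1.04, the log2 fold changes were −1.67 for OLFM4 and −1.06 for RETN, and CAMP did not pass (log2 −1.05, adjusted p = 0.119). Of 31 ribosomal protein genes, 26 fell over all genes and 29 adjusted over the list alone, led by RPS16 (85.5 ± 33.1 to 35.7 ± 11.9 CPM, adjusted p = 0.00198), RPL10A (log2 −0.88) and RPL22 (log2 −1.18). The ribosomal list had a median of −0.83 (camera adjusted p = 1.08e-11, 0.777 with an estimated correlation).

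The gene that rose with the smallest p was VAMP2 (ENSG00000220205.8, chromosome 17, 8159149 to 8163546), a vesicle fusion protein, from 7.12 ± 1.79 CPM in normal to 23.2 ± 11.3 CPM in humoral libraries (log2 1.70, SE 0.26, adjusted p = 0.000462; SD, n = 12 and 12). KSR1, a scaffold of the RAS pathway, rose from 19.0 ± 4.48 to 57.3 ± 30.9 CPM (log2 1.59, SE 0.25, adjusted p = 0.000462). The log2 fold changes of SEC31B, TMEM63A, CBFA2T2, TRAPPC9, DNHD1, UBE2V1 and the pseudogene PGAM1P11 were 1.56, 1.66, 0.97, 1.31, 1.58, 1.79 and 2.63. GAPDH, a glycolytic enzyme, fell from 903 ± 204 to 419 ± 150 CPM (log2 −1.11, SE 0.20, adjusted p = 0.000669). LGALS1, the gene of galectin-1, fell from 105 ± 33.7 to 49.3 ± 17.8 CPM (log2 −1.09, SE 0.20, adjusted p = 0.000669). ATP5MC3, NDUFS6, CCDC115, UBXN1, YIPF5, CSTB and GTF2F1 fell as well, with log2 fold changes of −1.01, −1.09, −0.77, −0.83, −0.96, −0.88 and −1.02.

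By gene type, 1410 of the 4154 coding genes called between humoral and normal libraries were higher and 2744 lower, whereas 901 of 942 long non-coding RNA genes were higher and 41 lower. The direction of the split depended on the scaling: 4360 genes were higher and 2206 lower with the size factors of DESeq2, and 2925 higher and 3639 lower with TMM computed without globin genes. The median log2 fold change of all tested genes was 0.08 with TMM, 0.20 with DESeq2 size factors, −0.01 without globin genes and 0.30 with counts over both strands. No called list changed the sign of its median under any of these scalings.

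The gene calls between humoral and normal libraries went with the library class, while the 4 lists stayed past the threshold of camera with the class as a term and among intron-poor libraries. With the class term, 2 genes were called and 0 of the 32 named passed, although all kept their direction. Intron-poor libraries alone (4 humoral, 11 normal) gave 2 genes. Both settings called NXF3 (ENSG00000147206.16, chromosome X, 103075810 to 103093125), an RNA export factor, at a log2 fold change of 4.63 (adjusted p = 0.0273) with the class term. It exceeded 1 CPM in 1 of 12 humoral and 1 of 12 normal libraries. Both also called ENSG00000273686.4 (log2 3.10, adjusted p = 0.0485 with the class term), which measured 78.5 ± 166 against 9.65 ± 4.38 CPM. These genes were chosen after their values were seen. The cytotoxic and NK cell list had a median of −0.75 with the class term (camera adjusted p = 2.24e-10) and −0.86 among intron-poor libraries (5.98e-12). Immature neutrophil granules stood at −1.30 and −1.40 (0.00598 among intron-poor libraries). Classical monocytes stood at −0.26 (0.00843) with the class term and −0.51 (6.34e-05) among intron-poor libraries, and ribosomal proteins at −0.34 and −0.27 (0.00333). Among intron-rich libraries (8 humoral, a single normal) cytotoxic and NK cells stood at 0.39 and classical monocytes at −0.21. Classical monocytes (−0.16, 0.139) and ribosomal proteins (−0.049, 0.09999) were not called with surrogate variables.

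**Figure D2:**
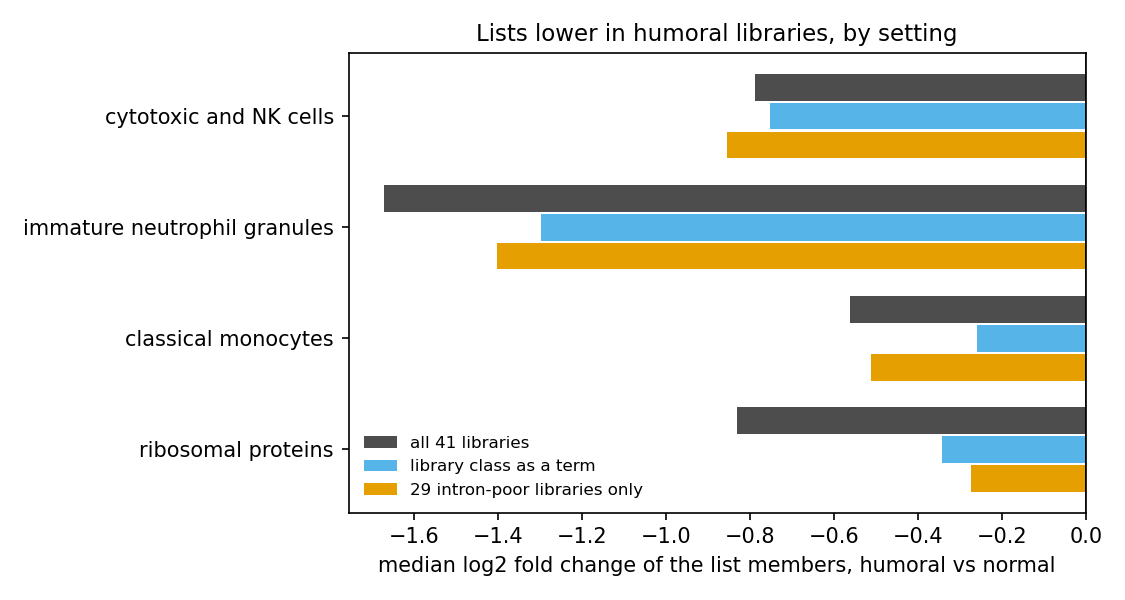
Median log2 fold change of list members, humoral against normal, for the 4 lists called with all 41 libraries (horizontal axis, log2). Bars give the value with all libraries, with the library class as a term, and among the 29 intron-poor libraries alone, where cytotoxic and NK cells stood at −0.79, −0.75 and −0.86.

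Per-library scores of the 4 lists, tested after these results were seen, were lower in humoral than in normal libraries. The mean score difference was −0.767 for classical monocytes (permutation p = 0.00036, adjusted p = 0.00774, 11 of 12 humoral libraries below the normal median) and −0.999 for ribosomal proteins (p = 0.00029, adjusted p = 0.00774, 10 of 12). It was −0.89 for cytotoxic and NK cells (p = 0.00194, adjusted p = 0.0167, 11 of 12) and −1.42 for immature neutrophil granules (p = 0.00986, adjusted p = 0.0471, 10 of 12). Among intron-poor libraries none of the 4 passed the adjustment over 11 tests (adjusted p from 0.107).

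Between mixed and normal libraries camera called interferon, non-classical monocyte and glucocorticoid response lists higher and red blood cell lists lower. None of its 8 calls passed with an estimated correlation (adjusted p from 0.0535) or fry (from 0.265). The interferon gamma list had a median of 1.25 over 17 genes (camera adjusted p = 3.4e-20, 0.0535 with an estimated correlation), with 0 members past the threshold over all genes and 5 adjusted over the list alone. GBP4, a guanylate-binding protein, measured 295 ± 174 against 124 ± 65.1 CPM (SD, n = 4 and 12), IDO1 36.8 ± 53.5 against 9.02 ± 6.04 CPM, and SOCS1 had a log2 fold change of 1.85. The type I interferon list had a median of 1.16 over 20 genes (camera adjusted p = 1.55e-17, 0.117 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Its leading members were the antiviral genes IFI6 (197 ± 228 against 68.1 ± 104 CPM), OAS1 (292 ± 346 against 115 ± 138 CPM) and OAS3 (log2 1.62). Both lists stayed called without mixed replicate 1, with a median of 0.28 (adjusted p = 0.000151) for interferon gamma and 0.12 (adjusted p = 0.0071) for type I interferon. Without normal replicate 1 the type I median was 1.90.

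Non-classical monocyte genes, which include the 3 chains of complement C1q, had a median of 0.75 over 8 genes in mixed against normal libraries (camera adjusted p = 2.14e-06, 0.0535 with an estimated correlation), 0 past the threshold over all genes and 3 adjusted over the list alone. C1QA measured 33.7 ± 40.3 against 8.63 ± 8.80 CPM, C1QB 23.3 ± 30.1 against 4.71 ± 6.35 CPM and C1QC 3.74 ± 5.08 against 0.615 ± 0.903 CPM (SD, n = 4 and 12). Without mixed replicate 1 the call was lost (median 0.42, adjusted p = 0.0678), and without normal replicate 1 the median was 1.13. Glucocorticoid response genes had a median of 1.63 over 13 genes (camera adjusted p = 1.11e-12, 0.0535 with an estimated correlation), with 0 members past the threshold over all genes and 9 adjusted over the list alone. OLAH measured 6.05 ± 7.66 against 0.798 ± 0.642 CPM, the complement receptor gene VSIG4 13.7 ± 13.1 against 2.72 ± 1.32 CPM and TPST1 50.9 ± 42.3 against 13.1 ± 10.1 CPM. The glucocorticoid list median without mixed replicate 1 was 0.63. The common rejection module is a published set of genes shared by rejecting grafts of several organs. Of its 11 genes 8 were measured, without TAP1 and PSMB9. It had a median of 0.41 over these 8 genes (camera adjusted p = 0.0049, 0.0535 with an estimated correlation), or 0.15 without mixed replicate 3, with 0 members past the threshold over all genes or adjusted over the list alone. Its members ISG20 (117 ± 69.8 against 76.0 ± 31.1 CPM), CXCL10 (log2 1.27) and CXCL9 (log2 1.26) had the smallest p.

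Erythroid genes had a median of −0.61 over 17 genes in mixed against normal libraries (camera adjusted p = 1.31e-08, 0.392 with an estimated correlation). BPGM, an enzyme of red cells, measured 278 ± 261 against 721 ± 411 CPM (SD, n = 4 and 12), and GYPB had a log2 fold change of −1.02. Globin genes had a median of −0.49 over 8 genes (camera adjusted p = 0.000437, 0.392 with an estimated correlation), with log2 fold changes of −5.31 for HBG1, −0.98 for HBD and −0.62 for HBA1. Immature neutrophil granules had a median of −0.70 over 18 genes (0.000789, 0.797 with an estimated correlation). Their log2 fold changes were −1.70 for MMP8, −1.22 for CAMP and −0.96 for TCN1. No member of these 3 lists passed, 0 over all genes and 0 adjusted over each list alone. The erythroid median was −0.32 without mixed replicate 2, −0.26 without mixed replicate 3, −1.72 without mixed replicate 4 and −0.36 without normal replicate 7. The globin call was lost without mixed replicate 2 (adjusted p = 0.176) or mixed replicate 3 (0.215), and its median was −0.32 without mixed replicate 1 and −2.96 without mixed replicate 4. The granule call was lost without mixed replicate 2 (0.178), mixed replicate 3 (0.770) or normal replicate 1 (0.131), and its median without mixed replicate 4 was −2.07. With the globin share as a covariate, the adjusted p was 0.121 for erythroid cells, 0.277 for globins, 0.557 for granules and 0.161 for the common rejection module.

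No gene passed the threshold between mixed and normal libraries with edgeR, where 495 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 4 each. MRC1 (ENSG00000260314.2, chromosome 10, 17809344 to 17911170), the mannose receptor of macrophages, had the smallest adjusted p, 0.0908, at 15.3 ± 19.0 against 2.67 ± 1.44 CPM (log2 2.51, SE 0.48; SD, n = 4 and 12). It passed without mixed replicate 2 (adjusted p = 0.0399), mixed replicate 4 (0.0355) or normal replicate 4 (0.0467). VAMP5 (23.3 ± 15.2 against 10.8 ± 3.15 CPM, adjusted p = 0.661) and ZNF366 (5.25 ± 5.61 against 1.69 ± 0.554 CPM, adjusted p = 0.661) followed. The pseudogene COX5BP6 and the kinase gene SGK2 had 0 counts in all 4 mixed libraries, at least 2.74-fold and at least 3.75-fold below normal, and DSP had a log2 fold change of −3.31. Per-library list scores gave no call for any of the 8 lists (for interferon gamma a mean difference of 1.03, exact p = 0.0626, adjusted p = 0.128, 4 of 4 mixed libraries above the normal median).

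Humoral against cellular libraries contrasts the antibody-driven with the T cell-driven form. Camera called classical monocyte and immature neutrophil granule lists lower and a B cell list higher in humoral libraries, and fry only the monocyte list. CD14 fell from 176 ± 103 CPM in cellular to 80.7 ± 36.6 CPM in humoral libraries (log2 −1.12, SE 0.27, adjusted p = 0.0127; SD, n = 13 and 12). LYZ fell from 4306 ± 1472 to 1936 ± 1584 CPM (log2 −1.15, adjusted p = 0.0128), and FCN1 from 1038 ± 467 to 596 ± 236 CPM (log2 −0.80, adjusted p = 0.0294). 3 of 12 classical monocyte genes were lower over all genes and 4 adjusted over the list alone, with a median of −0.68 (camera adjusted p = 0.000157, 0.784 with an estimated correlation, fry adjusted p = 0.0125). Its per-library score passed (adjusted p = 0.0167), unlike those of the other 6 called lists (from 0.0608). The median was −0.38 with the class term, −0.58 (4.27e-08) among intron-poor and −0.14 (0.704) among intron-rich libraries, where CD14 and FCN1 turned to 0.23 and 0.18 and 2 of the 7 called lists, cytotoxic and B cells, stayed called. CD22, an inhibitory receptor of B cells, rose from 9.97 ± 5.55 to 25.6 ± 16.1 CPM (log2 1.37, SE 0.40, adjusted p = 0.0253). FCRL1 rose from 23.6 ± 11.02 to 50.3 ± 31.1 CPM (log2 1.09, adjusted p = 0.0381), and TNFRSF13C, the receptor of the B cell survival factor BAFF, from 3.42 ± 2.19 to 8.85 ± 6.63 CPM (log2 1.39, adjusted p = 0.0400). Of 20 B cell genes, 4 rose over all genes and 5 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.0232, 0.784 with an estimated correlation). That median was 0.80 (3.11e-05) with the class term and 0.24 (0.0995) among intron-poor libraries. The B cell call was lost with counts over both strands (0.113) and without cellular replicate 10 (0.0616), 12 (0.0687), 1 (0.0514) or 5 (0.0705) or humoral replicate 4 (0.0618, median 0.35) or 5 (0.0604). Of the named genes, CD22 lost its call without humoral replicate 2, 3, 4 or 8 (adjusted p up to 0.0703) and FCN1 without cellular replicate 1, 6, 10 or 13 or humoral replicate 9 (0.0559). FCRL1 and TNFRSF13C lost it without cellular replicate 1, 2, 6, 8, 10 or 13 or humoral replicate 2, 3, 4, 7, 8 or 9 (up to 0.111 and 0.108). FCRL1 also lost it without cellular replicate 7, and TNFRSF13C without cellular replicate 5 or humoral replicate 10.

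Immature neutrophil granule genes had a median of −1.41 over 18 genes in humoral against cellular libraries, with 5 lower over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000177, 0.784 with an estimated correlation). The matrix protease gene MMP9 fell from 159 ± 157 to 54.5 ± 48.3 CPM (log2 −1.55, adjusted p = 0.0299). CRISP3 and TCN1 had log2 fold changes of −2.12 (adjusted p = 0.0375) and −1.54 (adjusted p = 0.0396). Without cellular replicate 7 the list median was −0.58, and neither CRISP3 (log2 −0.75, adjusted p = 0.341) nor TCN1 (log2 −0.61, adjusted p = 0.285) passed. Of the cytotoxic and NK cell genes, CST7 fell from 45.4 ± 25.4 to 24.8 ± 9.69 CPM (adjusted p = 0.0291), while GNLY (log2 0.86, adjusted p = 0.0574) and GZMB (log2 −0.77, adjusted p = 0.0667) did not pass. GZMB passed without cellular replicate 4, 5 or 12 or humoral replicate 5, 11 or 12, and GNLY without cellular replicate 3 or humoral replicate 5, 6 or 12. The list had 1 of 20 members past the threshold over all genes and 1 adjusted over the list alone, with a median of −0.33 (camera adjusted p = 0.0247, 0.784 with an estimated correlation). The median was −0.63 without humoral replicate 11 and −0.10 (0.0893) among intron-poor libraries. Its call was lost without cellular replicate 1 (0.0778) or 5 (0.0959) or humoral replicate 12 (0.107), 5 (0.0759), 6 (0.110) or 7 (0.0673). Of 31 ribosomal protein genes, 5 fell over all genes and 24 adjusted over the list alone, among them RPL8 (log2 −0.63), RPL30 (1012 ± 673 to 487 ± 369 CPM) and RPS19 (log2 −0.60). The ribosomal median was −0.62 (camera adjusted p = 4.84e-09, 0.784 with an estimated correlation). It was −0.20 (0.00149) with the class term and −0.24 (0.00576) among intron-poor libraries. CRISP3 and TCN1 were also lost without cellular replicate 10 or humoral replicate 1, 2, 3, 4, 8 or 9, TCN1 without cellular replicate 2 or humoral replicate 10, CST7 without cellular replicate 6 or 9 or humoral replicate 9 (adjusted p up to 0.0644) and MMP9 without cellular replicate 7, 9 or 13 (0.0655). RPL8 was lost without cellular replicate 11 (0.0535), RPL30 without cellular replicate 2, 3, 10 or 11 or humoral replicate 1, 7 or 9 (0.0732), and RPS19 without cellular replicate 1, 2, 8, 9, 10, 11 or 13 or humoral replicate 1, 7 or 9 (0.0815).

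Platelet and proliferation lists were called between humoral and cellular libraries with all 41 libraries, but not with the class as a term or among intron-poor libraries. The platelet median was −0.60 over 14 genes (camera adjusted p = 0.00126, 0.784 with an estimated correlation), against 0.19 (0.702) with the class term and −0.07 (0.0995) among intron-poor libraries, and it was −1.38 without humoral replicate 6. Its members PPBP (log2 −1.32, adjusted p = 0.0745), CLU (log2 −0.89, adjusted p = 0.120) and ITGA2B (log2 −1.03, adjusted p = 0.128) did not pass. All 3 passed without humoral replicate 6 (log2 −1.97, −1.36 and −1.78), PPBP also without cellular replicate 4, 5 or 12 or humoral replicate 12, and CLU without cellular replicate 12. The proliferation median was −0.56 over 15 genes (camera adjusted p = 0.0232, 0.784 with an estimated correlation), against 0.00 (0.540) and 0.02 (0.662). CDK1 (log2 −1.10, adjusted p = 0.0642), ZWINT (log2 −0.73, adjusted p = 0.0694) and CCNA2 (log2 −0.75, adjusted p = 0.106) did not pass. CDK1 and ZWINT passed without cellular replicate 5 or 12 or humoral replicate 5, 6, 11 or 12, ZWINT also without cellular replicate 4, and CCNA2 without humoral replicate 5 or 6. Both lists had 0 members past the threshold over all genes and 0 adjusted over the list alone. The proliferation call was lost without cellular replicate 3 (0.0933, median −0.20) or 7 (0.0554) or humoral replicate 10 (0.0689), 11 (0.101), 2 (0.0600), 3 (0.0546), 4 (0.111) or 8 (0.0568).

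In all, edgeR called 2416 genes (12.3%) between humoral and cellular libraries, 1535 higher and 881 lower. With TMM computed without globin genes the split was 1320 higher and 1996 lower. SRRM2 (ENSG00000167978.16, chromosome 16, 2752329 to 2772538), a splicing factor found in nuclear speckles, rose from 146 ± 60.5 to 358 ± 174 CPM (log2 1.29). VAMP2 rose from 8.58 ± 4.14 to 23.2 ± 11.3 CPM (log2 1.44) and APOBEC3F from 2.06 ± 0.717 to 4.80 ± 2.25 CPM (log2 1.20), and all 3 had an adjusted p of 0.00665. CBFA2T2, SLC25A25-AS1, BLCAP, SEC31B, PIK3R6, MIR3198-1 and DNHD1 rose as well, with log2 fold changes of 0.88, 1.63, 0.73, 1.31, 1.38, 2.31 and 1.36. LGALS1 fell from 103 ± 32.2 to 49.3 ± 17.8 CPM (log2 −1.07, adjusted p = 0.00665). GAPDH fell from 782 ± 294 to 419 ± 150 CPM (log2 −0.90, adjusted p = 0.00911) and ADGRG7 from 9.98 ± 20.97 to 0.158 ± 0.283 CPM (log2 −5.78, adjusted p = 0.00761). ZNF354A, CD63-AS1, SMPDL3A, DRAM1, NDUFS6, FAM200B and SDHAF3 fell as well, with log2 fold changes of −1.10, −0.81, −1.19, −0.78, −0.82, −0.88 and −0.87. With the class as a term 0 of the 33 named genes that had passed were called and all 33 kept their direction. Among intron-poor libraries 2 genes were called, NXF3 (log2 5.38, adjusted p = 0.0386) and ENSG00000273686.4 (log2 3.88, adjusted p = 0.0103). The count of 2416 lay between 1211 and 1538 without cellular replicate 1, 2, 6, 8, 9, 10 or 13, and between 1231 and 1592 without humoral replicate 1, 2, 3, 4, 7, 8 or 9. It lay between 3813 and 4951 without cellular replicate 4, 5 or 12, and between 4376 and 4968 without humoral replicate 5, 6, 11 or 12.

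Between mixed and cellular libraries camera called 13 lists, of which only the common rejection module was also called by fry or with an estimated correlation. It passed camera with both correlations and fry (median 0.64 over 8 genes, camera adjusted p = 0.000978, 0.0396 with an estimated correlation, fry adjusted p = 0.0386), but not fry for changes in either direction (adjusted p = 1.0), with 0 members past the threshold over all genes or adjusted over the list alone. NKG7, a granule protein of cytotoxic cells, measured 95.9 ± 28.3 against 57.5 ± 29.8 CPM (SD, n = 4 and 13), the T cell kinase LCK 175 ± 114 against 107 ± 46.5 CPM and the interferon-induced nuclease ISG20 117 ± 69.8 against 79.6 ± 20.99 CPM. The mean score was 0.647 higher in mixed libraries, 4 of which lay above the cellular median (exact p = 0.00336 over 2380 splits, adjusted p = 0.0236), and the list median without mixed replicate 3 was 0.42. The scores of the other 12 lists did not pass (adjusted p from 0.0608). Cytotoxic and NK cell genes had a median of 0.74 over 20 genes (camera adjusted p = 1.26e-10, 0.165 with an estimated correlation). TBX21 measured 57.6 ± 25.5 against 28.02 ± 12.7 CPM and CD8B 67.5 ± 68.2 against 27.5 ± 14.6 CPM, and S1PR5 had a log2 fold change of 1.03. 0 of its members passed over all genes and 0 adjusted over the list alone.

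Interferon and non-classical monocyte lists were called higher in mixed than in cellular libraries, and these calls rested on mixed replicate 1. The type I interferon list had a median of 1.43 (camera adjusted p = 2.53e-10, 0.425 with an estimated correlation). OAS2 measured 246 ± 214 against 84.1 ± 19.6 CPM, with log2 fold changes of 1.63 for OAS1 and 2.02 for OAS3 (SD, n = 4 and 13). The interferon gamma list had a median of 1.10 (camera adjusted p = 1.67e-10, 0.244 with an estimated correlation), with log2 fold changes of 1.29 for GBP4, 2.07 for IDO1 and 1.69 for SERPING1. Non-classical monocyte genes had a median of 1.02 (camera adjusted p = 9.94e-06, 0.146 with an estimated correlation), with log2 fold changes of 2.64 for C1QC, 2.10 for C1QB and 1.59 for C1QA. 0 members of these lists passed over all genes, and 5 of 20, 4 of 17 and 3 of 8 adjusted over the list alone. Without mixed replicate 1 the medians were 0.44 (adjusted p = 0.213), 0.20 (0.0636) and 0.43 (0.0881). Glucocorticoid response genes had a median of 0.54 (camera adjusted p = 0.0101, 0.611 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. TSC22D3 measured 1079 ± 807 against 619 ± 466 CPM, with log2 fold changes of 1.51 for VSIG4 and 0.95 for FKBP5. That call was lost without mixed replicate 1 (0.886) or mixed replicate 4 (0.145), and its median was 0.89 without cellular replicate 2 and 0.94 without mixed replicate 3.

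Camera called another 4 lists higher in mixed than in cellular libraries. T cell genes had a median of 0.30 (camera adjusted p = 0.0202, 0.796 with an estimated correlation) and T cell activation and checkpoint genes of 0.38 (0.0344, 0.425 with an estimated correlation). Plasma cell genes had a median of 0.43 (0.0139, 0.425 with an estimated correlation) and ribosomal protein genes of 0.24 (0.0139, 0.796 with an estimated correlation). No member of these lists passed, 0 over all genes and 0 adjusted over each list alone. Log2 fold changes were 0.62 for CD247, 0.70 for LCK and 0.74 for CD3G among T cell genes, and 0.96 for CXCR3, 0.31 for HAVCR2 and 0.80 for LAG3 among activation genes. They were 0.80 for PDIA4, 1.77 for TNFRSF17 and 1.04 for MZB1 among plasma cell genes, and 0.51 for RPL3, 0.40 for RPS19 and 0.35 for RPS2. The T cell call was lost without cellular replicate 2 (adjusted p = 0.0928), 3 (0.115), 6 (0.0642) or 7 (0.155) or mixed replicate 2 (0.722) or 3 (0.577, median −0.089), and its median was 0.55 without mixed replicate 1 and 0.64 without mixed replicate 4. The activation call was lost without cellular replicate 13 (0.05002), 2 (0.0928), 3 (0.0777), 6 (0.0648) or 7 (0.0994) or mixed replicate 2 (0.247) or 3 (0.344), with medians of 0.58 without mixed replicate 1 and 0.61 without mixed replicate 4. The plasma cell call was lost without mixed replicate 3 (0.799, median −0.16), and its median without mixed replicate 4 was 0.73. The ribosomal call was lost without cellular replicate 12 (0.153), 4 (0.0629), 5 (0.287) or 7 (0.0561) or mixed replicate 2 (0.244) or 3 (0.733, median −0.11). The ribosomal median was 0.38 without mixed replicate 1, 0.42 without mixed replicate 4, −0.03 (adjusted p = 0.217) among intron-poor libraries and 0.07 (0.821) with the class term.

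Camera called erythroid, globin and immature neutrophil granule lists lower in mixed than in cellular libraries (fry adjusted p from 0.650). The median was −0.94 for erythroid genes (camera adjusted p = 5.92e-06, 0.528 with an estimated correlation) and −0.64 for globins (0.0148, 0.605 with an estimated correlation). It was −0.48 for immature neutrophil granules (0.0344, 0.796 with an estimated correlation). Of their members, 0 passed over all genes and 0 adjusted over each list alone. Log2 fold changes were −1.45 for GYPB and −1.08 for KLF1. They were −3.59 for HBG1, −1.04 for HBM and −1.26 for HBG2, and −1.39 for CRISP3, −1.60 for MMP8 and −0.84 for MMP9. The erythroid median was −0.37 without cellular replicate 3 and −2.17 without mixed replicate 4. The globin call was lost without cellular replicate 3 (adjusted p = 0.113) or mixed replicate 1 (0.0636), 2 (0.346) or 3 (0.548), and its median was −2.56 without mixed replicate 4. The granule call was lost without cellular replicate 2 (0.0640), cellular replicate 7 (0.618, median 0.25) or mixed replicate 2 (0.558) or 3 (0.733), and its median was −1.78 without mixed replicate 4. With the globin share as a covariate 7 lists were called in place of 13, none of them lower.

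MRC1 was the only gene edgeR called between mixed and cellular libraries, where 994 had an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 2. It measured 15.3 ± 19.0 against 2.12 ± 1.26 CPM (log2 2.84, SE 0.47, adjusted p = 0.0063; SD, n = 4 and 13). Without mixed replicate 1 its log2 fold change was 1.44 (adjusted p = 0.851), and no gene was called. VAMP5 (log2 1.12, adjusted p = 0.604) and the aminopeptidase gene LAP3 (308 ± 296 against 102 ± 35.1 CPM, adjusted p = 0.857) followed without passing. COX5BP6 and SGK2, at 0 counts in all 4 mixed libraries, were at least 3.81-fold and at least 5.39-fold lower, and ADGRG7 had a log2 fold change of −8.11, also without passing.

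The 3 complement C1q genes, MRC1, MSR1 and VAMP5 were higher in mixed than in humoral libraries. C1QA (ENSG00000173372.16, chromosome 1, 22636506 to 22639608) rose from 3.41 ± 1.76 CPM in humoral to 33.7 ± 40.3 CPM in mixed libraries (log2 3.30, SE 0.56, adjusted p = 0.00319; SD, n = 12 and 4). C1QB rose from 1.82 ± 1.06 to 23.3 ± 30.1 CPM (log2 3.65, SE 0.64, adjusted p = 0.0038). C1QC rose from 0.155 ± 0.137 to 3.74 ± 5.08 CPM (log2 4.48, SE 0.76, adjusted p = 0.00319). MRC1 rose from 1.83 ± 1.30 to 15.3 ± 19.0 CPM (log2 3.03, SE 0.48, adjusted p = 0.00138). MSR1, a scavenger receptor, rose from 4.21 ± 2.26 to 20.3 ± 12.9 CPM (log2 2.25, SE 0.39, adjusted p = 0.00346). VAMP5, a vesicle membrane protein, had the smallest adjusted p, 5.11e-05, and rose from 6.11 ± 1.94 to 23.3 ± 15.2 CPM (log2 1.93, SE 0.26). Without mixed replicate 1 the log2 fold changes were 1.70 for MRC1, 2.11 for C1QA, 2.30 for C1QB and 2.93 for C1QC, each still called. With the class as a term only VAMP5 was called (log2 1.78, adjusted p = 0.0077), and among intron-poor libraries no gene by edgeR. The non-classical monocyte list had a median of 0.88, with 3 of 8 members higher over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00202, 0.415 with an estimated correlation). Its call was lost without mixed replicate 1 (adjusted p = 0.102).

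Cytotoxic and NK cell genes were higher in mixed than in humoral libraries, 10 of 20 over all genes and 15 adjusted over the list alone, with a median of 1.14 (camera adjusted p = 1.4e-07, 0.415 with an estimated correlation). PRF1 rose from 105 ± 68.0 to 267 ± 25.7 CPM (log2 1.34, adjusted p = 0.0244). TBX21 rose from 22.2 ± 15.6 to 57.6 ± 25.5 CPM (log2 1.37, adjusted p = 0.0255), and S1PR5 from 14.2 ± 10.97 to 42.4 ± 17.5 CPM (log2 1.57, adjusted p = 0.0205; SD, n = 12 and 4). Classical monocyte genes had a median of 0.83 (camera adjusted p = 0.000614, 0.415 with an estimated correlation), with 3 of 12 members higher over all genes and 6 adjusted over the list alone. CD163, a scavenger receptor for haemoglobin, rose from 61.0 ± 65.9 to 219 ± 195 CPM (log2 1.85, adjusted p = 0.0281). LYZ rose from 1936 ± 1584 to 4636 ± 2085 CPM (log2 1.26, adjusted p = 0.0350), and FCN1 from 596 ± 236 to 1243 ± 240 CPM (log2 1.06, adjusted p = 0.0380). In the interferon gamma list, 4 of 17 genes were higher over all genes and 11 adjusted over the list alone (median 1.11, camera adjusted p = 2.49e-05, 0.633 with an estimated correlation). CXCL10, a chemokine that attracts activated T cells, rose from 3.16 ± 4.00 to 18.7 ± 18.6 CPM (log2 2.53, adjusted p = 0.0311). GBP1 rose from 238 ± 159 to 696 ± 586 CPM (log2 1.55, adjusted p = 0.0414), and APOL1 had a log2 fold change of 1.05 (adjusted p = 0.0382). Without mixed replicate 1, CD163 (log2 1.13, adjusted p = 0.166), CXCL10 (log2 1.59, adjusted p = 0.193), GBP1 (log2 0.88, adjusted p = 0.271), APOL1 (0.181), LYZ (0.0558), FCN1 (0.0716) and the interferon gamma list (median 0.61, adjusted p = 0.102) did not pass. Without mixed replicate 2 none of these 9 named genes passed (adjusted p from 0.0651 for CD163 to 0.171 for LYZ). TBX21 (0.0701), LYZ and FCN1 were lost without mixed replicate 3, LYZ, FCN1, APOL1 and GBP1 without humoral replicate 1, 7 or 9, CXCL10 without humoral replicate 7 or 9, and APOL1 and GBP1 without mixed replicate 4. The type I interferon list had a median of 1.05 with 0 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.00688, 0.865 with an estimated correlation). IFIT2 (log2 1.49, adjusted p = 0.0755), IFIT3 (1.57, 0.0877) and IFI6 (1.47, 0.0947) led it without passing, but IFIT2 passed without humoral replicate 6 or 12, IFIT3 without 6 and IFI6 without 2. The type I call was lost without mixed replicate 1 (median 0.10, adjusted p = 0.784) or humoral replicate 11 (0.0768).

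Mean scores were higher in 4 of 4 mixed libraries than the humoral median for cytotoxic and NK cells (difference 1.07, exact p = 0.00385, adjusted p = 0.0236), classical monocytes (0.887, exact p = 0.00549, adjusted p = 0.0295) and non-classical monocytes (1.48, exact p = 0.00165, adjusted p = 0.0167). The scores of interferon gamma (adjusted p = 0.0992), type I interferon (0.297) and ribosomal proteins (0.102) did not pass. Ribosomal protein genes had a median of 0.88 between mixed and humoral libraries, with 6 of 31 members higher over all genes and 14 adjusted over the list alone (camera adjusted p = 6.9e-09, 0.633 with an estimated correlation). RPS19 (log2 1.0), RPS2 (log2 0.86) and RPL18 (log2 0.88) were among them. Without mixed replicate 3, RPL18 stood at 0.54 (adjusted p = 0.230), and RPS19 (0.128) and RPS2 (0.134) did not pass. Without mixed replicate 2 none of the 3 passed (from 0.0766), RPL18 was also lost without humoral replicate 1, 7 or 9 and RPS2 without humoral replicate 7. With the class as a term the ribosomal median was 0.30 (0.0402), and among intron-poor libraries 0.18 (0.205). Classical monocytes stood at 0.40 with the class term and 0.56 among intron-poor libraries, and cytotoxic and NK cells at 0.98 and 0.90.

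edgeR called 1825 genes (9.32%) between mixed and humoral libraries, 1231 higher and 594 lower. With the size factors of DESeq2 the split was 846 higher and 836 lower. PLAAT4 rose from 42.3 ± 16.6 to 109 ± 32.1 CPM and HCST from 9.37 ± 3.78 to 23.3 ± 5.52 CPM. GIMAP2 rose from 74.2 ± 31.2 to 197 ± 66.1 CPM and NDUFS6 from 7.27 ± 2.52 to 18.2 ± 3.87 CPM (SD, n = 12 and 4). The potassium channel gene KCNC4 fell from 10.4 ± 5.73 to 1.49 ± 0.716 CPM (log2 −2.77, adjusted p = 0.0182) and SEC31B from 19.2 ± 8.34 to 6.08 ± 1.85 CPM (log2 −1.65, adjusted p = 0.0200). SGK2 and COX5BP6, with 0 counts in the 4 mixed libraries, were at least 21.6-fold and at least 10.9-fold lower than in humoral libraries (adjusted p = 0.0163 and 0.0111). MHENCR, PPP1R3E, C4orf46P2, FAM229A, CACNA1F and PROSER3 fell as well, with log2 fold changes of −1.37, −1.71, −1.53, −1.85, −3.15 and −1.56. The number of genes called was 78 without mixed replicate 2, 647 without mixed replicate 3 and 1129 without mixed replicate 1. It was 635 without humoral replicate 7, 740 without humoral replicate 9, 1020 without humoral replicate 1, 3006 without humoral replicate 6, 3493 without humoral replicate 12 and 4155 without humoral replicate 11. SGK2, SEC31B, MHENCR, FAM229A, CACNA1F and PROSER3 were lost without mixed replicate 2 (adjusted p from 0.0515 to 0.0727) and C4orf46P2 without mixed replicate 3 (0.0534).

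**Figure D3:**
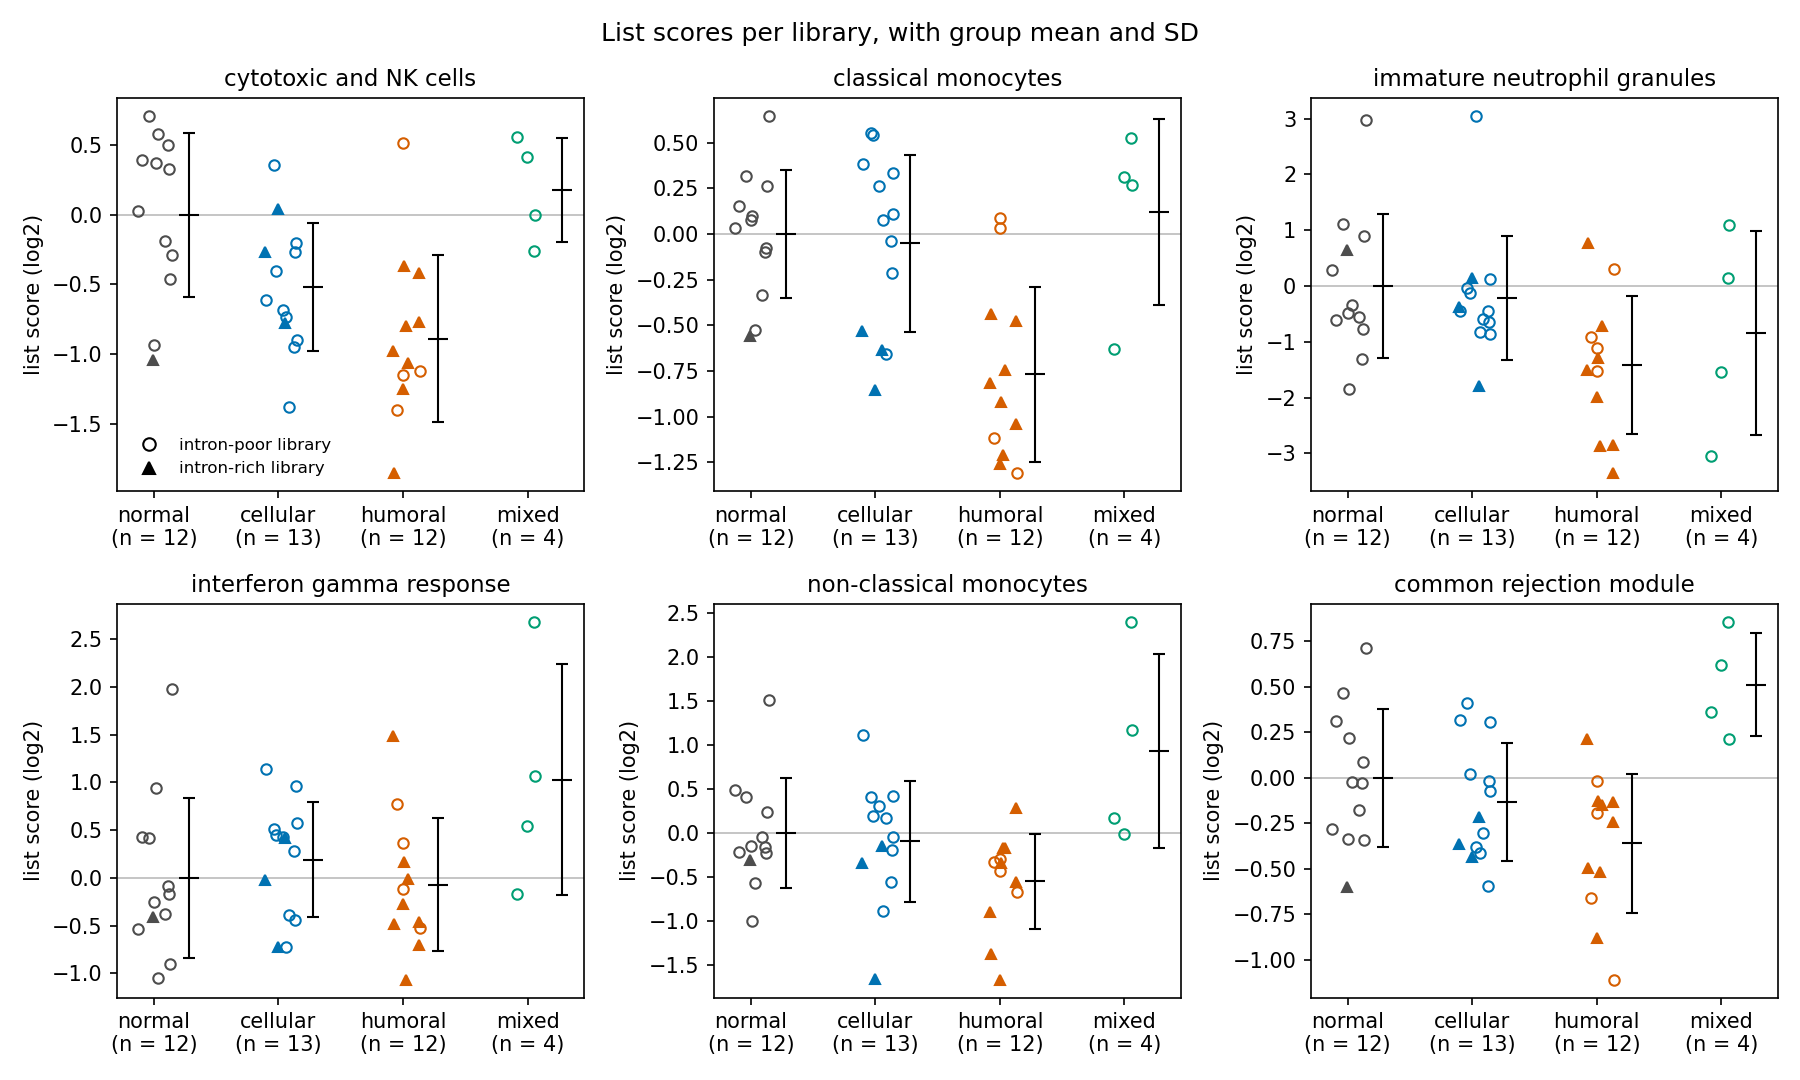
List scores (vertical axis, mean log2 CPM of the list members relative to the mean of the normal libraries) of 6 lists for each library by group, with group mean ± SD beside the points. Open circles are intron-poor and filled triangles intron-rich libraries, and 4 of 4 mixed libraries lay above the humoral median for cytotoxic and NK cells and for both monocyte lists.

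A joint test over the 4 groups called 4548 genes (23.2%), beside 7093 at an unadjusted p under 0.05, and 8 with the library class as a term. Fold changes of cellular and of humoral against normal, which share the normal libraries, correlated across genes (not independent replicates) with r = 0.542 and a covariance of 0.120. Unchanged groups simulated against the same controls gave a mean r of 0.473 (−0.024 to 0.771 over 100 draws) and a covariance of 0.0476, which leaves 0.0729. Library class, unequal among these groups, was not removed from it. With normal libraries split between the comparisons, r averaged 0.292 (0.039 to 0.523). Both comparisons shared 0 calls higher (0.349 expected of independent lists) and 1 lower (0.145 expected).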

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

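The tests of explanations and of other splits given here were chosen only after the results were seen, except the test of a humoral difference present in both library classes.

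Of 114 results examined in the 4 mixed libraries or outside the sense counts (79 genes, 26 lists and 9 library measures), 7 had 1 mixed library far from the other 3 (4 genes, 1 list and 2 measures), where chance gives about 1 in 20. MRC1 stood at a log2 CPM of 5.45 in mixed replicate 1 and between 2.42 and 2.73 in the others. HBG1 stood at −1.68 in mixed replicate 4 and −3.00 in the others, and the globin share of that library was 2.43% against 0.0632% to 0.191%. In mixed replicate 3, MMP9 stood at 4.08 (others 6.58 to 6.96), C4orf46P2 at 0.047 (others 1.41 to 1.66), the mature neutrophil list score at −2.00 (others 0.14 to 0.53) and the level of long coding genes at 8.64 CPM (others 3.96 to 4.23). In the opposite-strand counts, the median share of a library's counts on the opposite strand was 7.35% in humoral and 5.31% in normal libraries (permutation test, adjusted p = 0.00756).

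Many genes differed between humoral and normal libraries. Within the cellular group, 3 intron-rich differed from 10 intron-poor libraries in the direction of those genes by a mean log2 of 0.867 (exact p = 0.0035 over 286 splits, 91.5% of genes with the same sign). With the class as a term 2 calls were left, the median signed log2 fold change going from 0.88 (median SE 0.248) to 0.38 (0.223), so the calls ended mainly because folds shrank. The tables argue against lower depth as the whole cause (5645 genes called after thinning, 5219 of the original 6260). The added sense-intronic share was 0.0288 times as large on the opposite strand, against genomic DNA as its source. Long coding genes had opposite-strand medians of 17.8 (intron-rich) and 9.65 CPM (intron-poor), so DNA is not excluded. A library class difference, as in blood or RNA handling, is a candidate explanation for most calls, with no batch labelled. A humoral difference present in both classes stays open: genes called between humoral and cellular among intron-rich libraries had a mean signed difference of −0.134 between 4 humoral and 10 cellular intron-poor libraries (exact p = 0.152 over 1001 splits, 25.03% of genes with the same sign) and of 0.000732 against 11 normal ones (exact p = 0.993), which gives it no support without excluding it.

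Interferon and non-classical monocyte lists were higher in mixed libraries. Without mixed replicate 1 the interferon gamma median against normal went from 1.25 to 0.282, so a single library may carry most of the size. A difference of the mixed group as a whole stays open: 4 of 4 mixed libraries lay above the normal median and 1 above the highest normal library, with an exact p of 0.0626 over 1820 splits.

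Humoral replicate 12 and normal replicate 5 had 102.0 and 101.9 CPM in 19 long coding genes, where the next highest library had 39.7 and the median of the others was 7.17. Counts in 383 olfactory receptor genes were nearly as frequent on the opposite as on the sense strand (ratios 1.01 and 0.812, others up to 0.644 with a median of 0.113). Receptor levels of 200 and 240 CPM lay below humoral replicate 9 (309). Genomic DNA in these 2 libraries is a candidate source. Receptor transcription stays open: counts per receptor gene over pseudogene, at most 1.505, lay within the others' range (0.497 to 7.90, median 2.04).

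The 41 libraries were split in 60 ways into groups of the same sizes, the real split included. Chance can be excluded at this level for the gene counts of humoral against normal (6260, highest other 2902), humoral against cellular (2416, 1281), mixed against humoral (1825, 55) and any of the 4 groups (4548, 107), each with 1 of 60 as large. It stays open for cellular against normal (3, 2 of 60 as large). That count fell to 1 without normal replicate 3 or 9, and 16 of 60 splits gave at least 1. Its highest other was 1199, which points to a structure of the samples: in that split the groups' shares of intron-rich libraries differed by 45.5 points (14.7 in the real one). In the split with 2902 calls they differed by −58.3 points (58.3 in the real one). For mixed against normal (0 genes, highest other 7) this decides nothing, since any of the 60 splits gives at least 0. Chance cannot be excluded for mixed against cellular (1 gene, highest other 22, 28 of 60). Nor can it for any count of lists called by camera with the preset correlation: cellular against normal 5 (highest other 17, 55 of 60), humoral against normal 4 (17, 58 of 60), mixed against normal 8 (15, 43 of 60), humoral against cellular 7 (20, 52 of 60), mixed against cellular 13 (20, 17 of 60) and mixed against humoral 6 (20, 49 of 60).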

How the results depend on the processing

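The settings with the library class, the intronic share, intron-poor or intron-rich libraries, thinning and leaving out 2 libraries were chosen only after the data were examined. Of 204 settings of the counts of genes and lists and of the correlation, 114 stayed within 1.5 times the value reported and 90 did not. Of the values of named genes, 6766 kept their direction and side of the threshold, 704 lost the call, 75 gained one and 33 changed sign. The simulation, without library class or correlation between genes, recovered 24% of 2-fold changes for mixed against normal, 41% for cellular and 48% for humoral against normal. Unless stated, the cause was not tested.

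With DESeq2, 4 genes were called for mixed against normal, 3868 for humoral against cellular, 4 for mixed against cellular and 3594 for mixed against humoral, and with its size factors in edgeR 1 for mixed against normal. limma-voom called 0 genes for cellular against normal, 12085 for humoral against normal, 4 for mixed against normal, 11305 for humoral against cellular, 2 for mixed against cellular, 7642 for mixed against humoral and 12005 for any of the 4 groups. Without a low-count filter the counts were 2 for mixed against normal, 648 for humoral against cellular, 2 for mixed against cellular and 45 for mixed against humoral. The stricter filter gave 0 for cellular against normal and 1 for mixed against normal. Counts over both strands gave 2995 genes for mixed against humoral, and 8, 8 and 11 lists for cellular against normal, humoral against normal and humoral against cellular. The median log2 fold change of all genes was −0.12 for mixed against humoral, −0.25 with DESeq2 size factors and −0.41 over both strands. Over both strands it went from 0.055 to 0.19 for humoral against cellular and from −0.025 to −0.15 for mixed against cellular. With the globin share as a covariate 1 gene was called for cellular against normal and 2 for mixed against cellular, with 8 and 7 lists. With surrogate variables, of which the nearest to the library class had an absolute correlation of 0.893 with it, 1 gene was called for mixed against normal, 0 in the other 5 comparisons and 0 for any group, with 10 lists for cellular against normal and 7 for humoral against normal. These held, in the same direction, 1 of the 5 and 2 of the 4 lists called without these variables. Fits of only the 2 groups compared gave 0 genes for cellular against normal, 994 for humoral against cellular, 0 for mixed against cellular and 3 for mixed against humoral. A log2 fold change over 1 was met by 2614, 894 and 924 of the genes called for humoral against normal, humoral against cellular and mixed against humoral, by construction fewer. With an estimated correlation 1 list was called for mixed against cellular and 0 in each other comparison, and fry called 0, 0, 1 and 1 lists for cellular against normal, mixed against normal, humoral against cellular and mixed against cellular. Splitting the normal libraries lowered the correlation of fold changes to 0.292.

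With the library class as a term the counts were 2 for humoral against normal, 1 for mixed against normal, 0 for humoral against cellular, 1 for mixed against humoral and 8 for any group, with 11 lists for humoral against normal and 14 for mixed against humoral. With the intronic share they were 240, 1, 0, 4 and 34, with 12 and 15 lists and 8 lists for cellular against normal. Intron-poor libraries gave 2, 1, 2, 0 and 5 genes in the same order and 1 for cellular against normal, with 7 and 14 lists and 12 for cellular against normal. Intron-rich libraries, with a single normal library assumed to vary like the other groups, gave 0 genes and 8 lists for cellular against normal, 1108 genes for humoral against normal and 825 for humoral against cellular. Thinning left 1 gene for cellular against normal. Without the 2 libraries with reads in long coding genes, 0 genes were called for cellular against normal, 4983 for humoral against cellular and 3967 for mixed against humoral, with 4 lists for humoral against cellular.

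The replicate numbers do not pair the samples: 48 same-numbered pairs had a mean correlation of −0.026 (−0.541 to 0.491), and 4 of 41 libraries correlated best with their own number. With the replicate number as a block 0 genes were called for cellular against normal, humoral against cellular and mixed against cellular, 1 for mixed against humoral and 5888 for humoral against normal, and HBG2 for mixed against cellular turned to 0.99.

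These log2 fold changes changed sign. For mixed against cellular, MMP8 was 0.12 with DESeq2, MZB1 −0.24 with limma-voom, and HBM 0.14 with the globin share. With surrogate variables, FCRL1 and TNFRSF13C were −0.087 and −0.072 for humoral against cellular, HBM and HBG2 0.37 and 0.45 for mixed against cellular, and IFIT2, IFIT3 and FCN1 −0.40, −0.23 and −0.0051 for mixed against humoral. For humoral against cellular, CLU was 0.015 with the class term and MIR3198-1 −0.76 among intron-poor libraries. Among intron-rich libraries, cellular against normal gave −1.40 for SNORD3C, 0.15 for TRDC, 0.26 for CD2, 0.51 for TBX21, 0.65 for PRF1, 0.77 for S1PR5 and −0.075 for IL1R2, humoral against normal 0.28 for PRF1, and humoral against cellular 0.23 for CD14, 0.18 for FCN1, 0.34 for CLU and 0.25 for ITGA2B.

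Leaving out each library in turn gave 1 to 3 genes for cellular against normal, 5561 to 7417 for humoral against normal, 0 to 1 for mixed against normal, 1211 (without cellular replicate 10) to 4968 (without humoral replicate 11) for humoral against cellular, 0 to 1 for mixed against cellular, 78 (without mixed replicate 2) to 4155 (without humoral replicate 11) for mixed against humoral and 3368 to 5895 for any group. List counts ran from 3 (without cellular replicate 2) to 10 (without normal replicate 1) for cellular against normal, 4 to 6 for humoral against normal, 7 to 14 (without mixed replicate 3) for mixed against normal, 5 to 8 for humoral against cellular, 8 (without mixed replicate 1) to 16 for mixed against cellular and 3 (without mixed replicate 1) to 13 (without mixed replicate 3) for mixed against humoral. For mixed against cellular, HBG2 ran from −3.65 to 1.23, LAG3 from −0.015 to 1.07, MMP8 from −2.22 to 0.15, MZB1 from −0.66 to 1.40, RPL3 from −0.016 to 0.75, RPS19 from −0.0029 to 0.61 and TNFRSF17 from −0.36 to 2.15, and SOCS1 for mixed against normal ran from −0.055 to 2.18.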

Other observations

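Several lists had no camera call in the 6 comparisons with all libraries and no covariate. Mature neutrophil genes (15 measured) had medians from −0.47 to 0.37 (smallest camera adjusted p = 0.139), dendritic cell genes (8) from −0.26 to 0.01 (0.268), eosinophil and basophil genes (13) from −0.21 to 0.49 (0.121), and complement and Fc receptor genes (12) from −0.41 to 0.54 (0.0643). The published 17-gene blood set for acute kidney rejection, of which 16 genes were measured, had medians from −0.19 to 0.26 (0.205). Mitochondrially encoded genes (13) ranged from −0.32 to 0.16 (0.127), class II antigen presentation (3) from −0.48 to 0.67 (0.155) and immunoglobulin constant regions (3) from −0.45 to 1.52 (0.203). Each of these lists but dendritic cells was called in another setting or without 1 library. For humoral against normal, eosinophils and basophils stood at 0.57 (0.00966) with the library class as a term. For mixed against normal, mature neutrophils (0.000453) and complement and Fc receptors (8.62e-06) were called without mixed replicate 3.

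Genes of the major histocompatibility complex were nearly without counts. Of 198 coding genes on chromosome 6 between 28 and 34 Mb, 146 (73.7%) had a total under 10 counts over all 41 libraries, against 41 of 838 (4.89%) on the rest of the chromosome. Total counts were 3 for HLA-DRA, 6 for HLA-E, 4 for TAP1 and 0 for PSMB9 and TNF, while HLA-B had 59725 and HLA-C 15652, and B2M, whose product pairs with these HLA proteins and which lies on another chromosome, 711507. Outside the region, CCL4 and IGHM had 0 counts and IGHG1 17. How reads at alternate loci were counted is not given, and the cause was not tested. The class II and immunoglobulin values above rest on 3 of 9 and 3 of 13 members. This region and these genes were chosen after the values were seen.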
